A study of Mus musculus with 10 samples.

How the data were processed

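Total RNA from mouse KH2 embryonic stem cells with a doxycycline-inducible Sox17-V5 transgene was measured on 10 Illumina bead arrays, 5 labelled uninduced and 5 labelled induced for 48 h. Per the labels, RNA was extracted with Trizol and RNeasy columns with DNase I, checked on a Bioanalyser, and amplified to biotin-labelled cRNA (Ambion MessageAmp kit). The deposited values are 1 intensity per probe and array, on a linear scale. Judged from the authors' intensity values, background was subtracted, since 25.5% lie below 0. The 75th percentile is 250.0 on every array, so the 10 arrays were normalized to each other. Quantile normalization is inferred from this and is not stated, and the array medians differ slightly. The software that made them is not given in the sources used here. Array medians lay between 21.7 and 22.0 and single values between -19.0 and 24578. For arrays, their number limits the precision.

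A second deposited table holds signals and detection p values without normalization for 10 arrays, in 20 columns. Its columns carry sample numbers that occur in no label, so they could not be tied to samples, and the table was not used here. The test fixed before the data were examined was limma on values corrected and normalized with neqc from such signals. It was replaced by limma on the deposited normalized intensities, which had been fixed as an alternative. Gene lists, the rule for named genes, the grouping by label and the other alternatives were also fixed before the data were examined, apart from those said below to have been added.

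Of the 25697 probes, 23978 carry 1 gene symbol in the probe annotation, 23962 of them matched through the Entrez identifier, and 1719 carry none. Intensities under 0 were set to 0, 16 was added and log2 was taken. The background SD, 6.45, came from values below 0 mirrored about 0, and gave a background limit of 10.6 and a stricter limit of 15.0. A probe was tested if it lay above the limit on at least 5 of the 10 arrays, which kept 14985 probes for 10087 genes. Genes were represented by their probe with the highest mean over all arrays.

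Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjusted p values and a threshold of 0.05. Adjusted p values throughout come from limma. Differences of Sox17 between the labels were also tested by an exact permutation of the 10 arrays (252 arrangements, two-sided). Where the mean of a group, or 50% or more of its arrays, lay under the background limit, the fold change is a lower bound computed, without the added 16, with values raised to that limit, and is given as "at least". No fold is given where arrays of both groups lay under it. On simulated data with 200 changed probes, the comparison of labels recovered 99% of 2-fold and 100% of 4-fold changes, with 12 false calls among 211. These rates hold for the simulated data only. On the measured arrays the labels gave 2919 called probes, and a grouping other than by label gave up to 4016. With each array left out in turn, the calls ranged from 14 to 6821. The simulated rates are therefore not taken as the power or false-call rate of the label comparison. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

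The 26 gene lists cover naive pluripotency, general pluripotency, post-implantation epiblast, extraembryonic endoderm regulators and receptors, parietal endoderm, visceral endoderm, definitive endoderm, primitive streak and nascent mesoderm, endothelium, neural ectoderm, trophoblast, germ cell, the two-cell-like state, basement membrane and collagen processing, Wnt targets, Nodal and FGF feedback targets, BMP targets, embryonic fibroblast, simple epithelium and tight junction, cell cycle, p53 targets, ATF4 and amino acid stress, hypoxia and glycolysis, sterol synthesis, the Sox family and imprinted genes. Sox17 was left out of every list. A list was tested with at least 5 measured members by limma's camera with a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. The rule for named genes took Sox17, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose 5 arrays of each label do not overlap, up to 4 called members of each list, and the 2 most intense members of a list without a call.

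The arrays proved to fall into a pair of sets by their background pattern. Sets were found from 1356 probes of chemosensory receptor families (Olfr, Vmn1r, Vmn2r, Tas2r and Taar), most of which carry background only, by the largest gap along their first principal component. This family of probes was chosen after the data had been seen. The sets were used as a block, and description runs (title numbers 1 to 3 against 4 and 5, where the replicate numbers in the sample descriptions restart) were compared within a label and a set. That run comparison was added after seeing the data. It named 10 genes in each direction by the rule above, applied to the arrays labelled uninduced, and up to 4 called members of each list. A lone array in a group is assumed to vary like the arrays of the other groups.

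Alternatives were cyclic loess normalization, no filter, a stricter filter, an offset of 50, a floor at the background limit, the title number as a replicate block, the run as a block, each run alone, an intensity trend with robust hyperparameters, array weights, the average of a gene's probes, a count of non-overlapping probes, each array left out, and the set as a block or the first set alone. The stricter filter, the offset, the floor and the set were added after seeing the data. The title numbers did not pair the arrays: 4 of 5 numbered pairs correlated above 0.1, and 1 array correlated best with its own number. Of the 126 splits of the 10 arrays into 5 and 5, 100 were drawn at random, the labels' own included, and the other splits were counted by their larger direction.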

Results

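KH2 cells are mouse embryonic stem cells built to carry a transgene under doxycycline control, here Sox17 with a V5 tag. Sox17 is an HMG-box transcription factor of endoderm. Messenger RNA was measured on 10 Illumina bead arrays, of which 5 are labelled uninduced and 5 labelled induced for 48 h. Arrays are named here by label and title number, from uninduced 1 to induced 5. The replicate numbers in the sample descriptions run from 1 to 3 and then restart at 1 for titles 4 and 5 of each label, and these stretches are called run 1 and run 2. The labels do not say whether replicates are separate cultures, so p values measure the spread between samples, which may be technical. Of 25697 probes, 14985 for 10087 genes lay above background on enough arrays to be tested. Differences are given on the log2 scale of intensity plus 16, with the standard error after the sign ±, and intensities as mean ± SD.

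Sox17 was read first, because induction should raise it. On the arrays labelled uninduced, probe ILMN_2747986 had a mean intensity of 44.2 ± 17.2 (SD, n = 5), and on the arrays labelled induced 24.9 ± 23.8 (SD, n = 5). The difference of -0.66 ± 0.29 did not pass the test (adjusted p = 0.120, exact permutation p = 0.135). Arrays labelled uninduced 1 to 3 read 32.6, 32.1 and 30.5, and the arrays labelled uninduced 4 and 5 read 60.6 and 65.3. The array labelled induced 1 read 67.3, the highest of all, while those labelled induced 2 to 5 read 13.6, 11.99, 16.6 and 15.0. Probe ILMN_2784446 of the same gene was too dim to be tested and had means of 20.7 ± 12.9 and 10.05 ± 18.5 (SD, n = 5 each, exact permutation p = 0.190). It too was highest on the array labelled induced 1, at 42.9, followed by uninduced 5 at 35.4 and uninduced 4 at 32.2. A Sox17 probe outside the part carried by the transgene would check nothing, and the position of these probes is unknown here. Within run 2 alone Sox17 was lower on the arrays labelled induced (-1.31, adjusted p = 0.00268), and with array weights it was too (-0.77, adjusted p = 0.00457). Without the array labelled induced 1 the difference was -0.95 and passed the test. In run 2 alone and without induced 1, the label coincides with the array set described below. Array weights gave induced 1 a weight of 0.169. These results therefore cannot tell the label from the set. Within run 1 alone the Sox17 difference was -0.22 and did not pass (limma adjusted p = 0.776). With the array set as a block it turned to 0.51, a value that rests on the array labelled induced 1 alone.

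The arrays did not separate by label alone. Across all tested probes the first principal component held 56.7% of the variance and set the arrays labelled induced 2 to 5 (scores 26.8 to 36.5) apart from the other 6 (scores -24.1 to -18.4). The second, with 20.4%, set uninduced 1 to 3 and induced 2 and 3 (14.8 to 17.6) apart from uninduced 4 and 5 and induced 1, 4 and 5 (-17.5 to -13.3). Odorant, vomeronasal and taste receptor probes, most of which carry background only, gave the same division as the first component. Their rank correlation was 0.820 to 0.845 between arrays labelled induced 2 to 5, 0.433 to 0.528 among the other 6, and 0.416 to 0.517 across that division, over probes that are not independent replicates. These are called the first set (uninduced 1 to 5 and induced 1) and the second set (induced 2 to 5). In receptor probes the first set was hardly more alike (median 0.484) than arrays across the division (0.478). By background it is therefore a remainder, marked only by lacking the pattern of the second set. Across all tested probes its arrays did correlate more (0.988 to 0.996) than arrays across the division (0.968 to 0.979). Set and label were associated (Fisher's exact test, p = 0.0476), and 0 arrays labelled uninduced lie in the second set. The nearest array to induced 1 was uninduced 4 (r = 0.995 across probes).

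**Figure D1:**
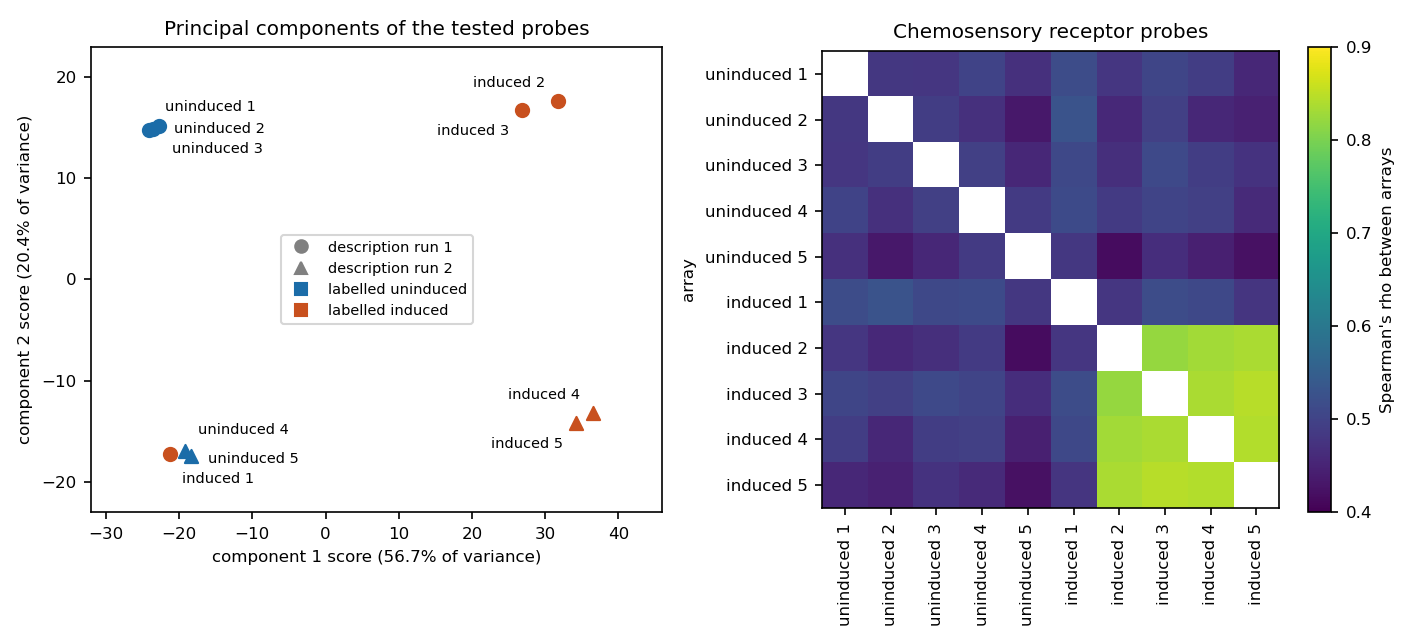
Left, principal component scores of the 10 arrays from the tested probes, by label (color) and description run (marker shape); right, Spearman's rho between arrays over 1356 chemosensory receptor probes. The arrays labelled induced 2 to 5 stand apart on the first component (26.8 to 36.5) and correlate with each other (0.820 to 0.845) more than any other pair does.

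The comparison of labels was made to ask which genes respond to 48 h of Sox17, but label and array set nearly coincide. Among genes whose arrays do not overlap between the labels, rises were found for Rbm14, which encodes a nuclear RNA-binding protein (142.0 ± 23.5 to 347 ± 101, SD, n = 5 each), and Klhl13, an adaptor of a ubiquitin ligase (23.1 ± 3.07 to 79.0 ± 34.7). Olfr536, an odorant receptor, read 63.1 ± 25.8 on the arrays labelled induced and lay under the background limit on 4 of the 5 labelled uninduced. Among genes whose 5 arrays per label do not overlap, the largest falls were those of Rif1, which acts in replication timing and DNA repair (367 ± 35.7 to 128 ± 96.5), and Jund, an AP-1 transcription factor (235 ± 43.0 to 75.7 ± 55.3). Zc3h13, a part of the RNA adenosine methyltransferase complex, fell from 2369 ± 265 to 917 ± 594.

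On the log2 scale Rbm14 rose by 1.16 ± 0.19, Klhl13 by 1.20 ± 0.22 and Grb2, the adaptor between receptor tyrosine kinases and Ras, by 1.10. A second Rbm14 probe rose less, by 0.41, and passed the test too. Where the mean of a group, or 50% or more of its arrays, lay under the background limit, a lower bound of the fold is given instead. Olfr536 rose at least 4.93-fold (adjusted p = 0.0188), the secretory pathway kinase Fam20c, under the limit on 1 of 5 arrays labelled uninduced, at least 3.67-fold, and Fam228b, under it on 3 of 5, at least 3.79-fold. On all 5 arrays labelled uninduced, 6 further genes lay under the background limit. Of these, Jph2, a junctophilin, rose at least 3.54-fold, the defensin gene Defb25 at least 3.26-fold, the pseudogene Phf8-ps at least 2.70-fold, the desmosomal cadherin Dsg4 at least 2.69-fold, the centrosomal gene Tacc2 at least 2.12-fold and Xlr5c at least 1.98-fold. On the array labelled induced 1 these 6 genes read 10.7 to 13.7, near the limit of 10.6. Olfr536, of a receptor family that marks the sets, read 18.2 there. These rises therefore rest mainly on induced 2 to 5, and a higher background of these probes on those arrays was not excluded. Among the falls, Rif1 fell by 1.60 ± 0.30 (adjusted p = 0.0206), Jund by 1.59 ± 0.28 and Zc3h13 by 1.57 ± 0.34. On induced 1 they read 298, 173 and 1863, just under the lowest array labelled uninduced (313, 183 and 1927). On induced 2 to 5 they read 63.5 to 115, 42.6 to 70.0 and 386 to 1103. Their changes with the set as a block, which rest on induced 1, were -0.28, -0.39 and -0.34. These falls too rest mainly on induced 2 to 5. Further falls were those of Clic6 (-1.34), the endocytosis gene Hip1 (-1.27), the cell polarity gene Mpp5 (-1.26), the calcium-regulated transcription factor Nfatc3 (-1.23), Rassf5 (-1.18) and the chromatin reader Zmynd8 (-1.17), with Clic6 under the limit on 2 of 5 arrays labelled induced and Hip1 and Rassf5 on 1. The transporter Abcg4 fell at least 2.30-fold and Map7d2 at least 2.69-fold, each under the limit on 4 of 5 arrays labelled induced, and the glycosyltransferase B4galnt2, under it on 3 of 5, at least 3.29-fold.

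Between the labels 2919 probes differed, 1358 higher and 1561 lower on the arrays labelled induced. They stand for 850 genes that rose and 1107 that fell, of which 148 changed at least 2-fold, 50 up and 98 down. Of the 71 tested receptor probes of the families that mark the sets, 14 were higher and 2 lower (22.5% called), beside 19.5% of all tested probes; the difference in share was not tested. With the set as a block, limma called 0 probes (724 at an unadjusted p under 0.05), and 0 of the 65 called genes among the 75 named by rule remained called. That block rests on 1 array labelled induced, induced 1, since the second set holds 0 labelled uninduced. Leaving out 1 array moved the number of called probes to 21, 34, 52 and 1864 without uninduced 1 to 4. It was 6821, 17, 639, 14 and 16 without induced 1 to 5. Without induced 1, label and set coincide. Of the 65 called named genes, the number still called was 3, 4, 8, 52 and 55 without uninduced 1 to 5, and 65, 2, 40, 2 and 2 without induced 1 to 5. Within run 1 alone limma called 0 probes, and without the filter on dim probes it called 289 higher and 260 lower. For the difference between labels to differ by run, limma called 0 probes (991 at an unadjusted p under 0.05).

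**Figure D2:**
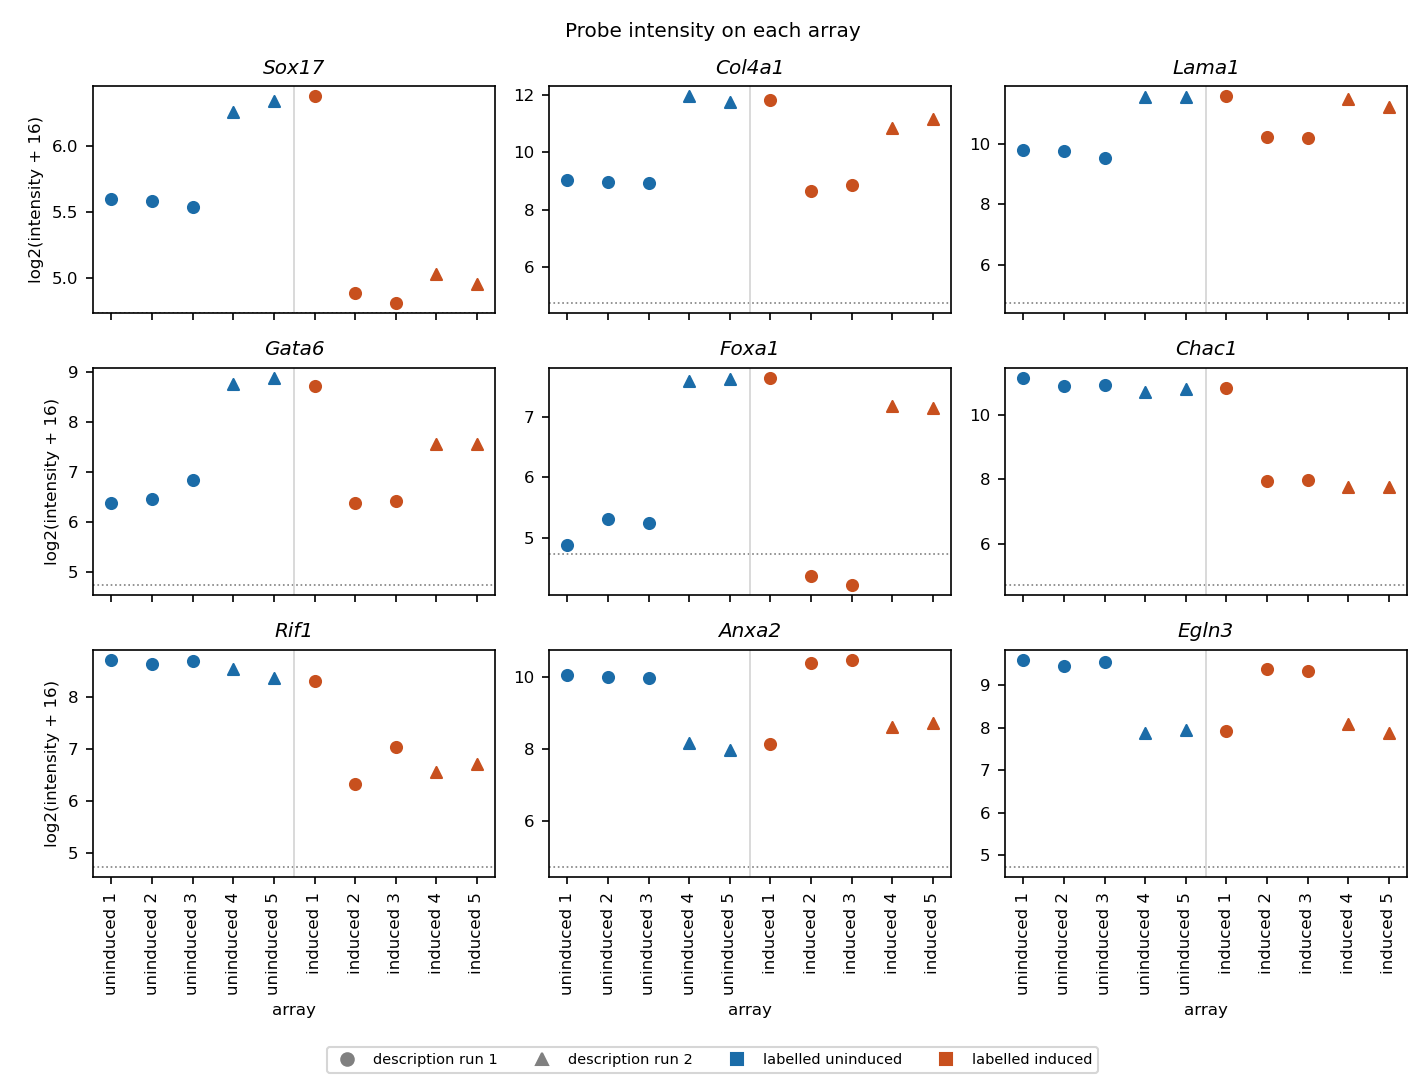
Intensity plus 16 on a log2 scale on each of the 10 arrays for 9 genes, colored by label, with circles for description run 1, triangles for run 2 and a dotted line at the background limit; the vertical axes differ between panels. Chac1 and Rif1 are low on the arrays labelled induced 2 to 5, while Col4a1 and Foxa1 are high on uninduced 4 and 5 and induced 1, 4 and 5.

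Genes of the ATF4 and amino acid stress list were lower on the arrays labelled induced. Of 15 measured, 0 rose and 6 fell (0 and 10 adjusted over the list alone), with a median of -0.35. Chac1, which degrades glutathione, fell by 2.43 ± 0.50 (adjusted p = 0.0209), from 1896 ± 218 to 537 ± 714 (SD, n = 5 each). The stress-response gene Nupr1 fell by 1.16 ± 0.22, the mitochondrial folate enzyme Mthfd2 by 0.73 ± 0.15 and the transcription factor Cebpb by 0.71 ± 0.15. Atf4 itself and Psat1, singled out after their values were seen, each fell by 0.40. This was the only list of the 25 tested that camera called (adjusted p = 0.00186), and it was not called with an estimated correlation (adjusted p = 0.893 with an estimated correlation). It followed the sets: Chac1 read 202 to 234 on the arrays labelled induced 2 to 5, 1814 on induced 1 and 1651 to 2235 on those labelled uninduced. The call was lost, and the median was -0.12, with the set as a block (adjusted p = 0.459).

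Pluripotency genes moved both ways between the labels. In the naive list of 15, Fbxo15 rose (0.38 ± 0.11), while Klf4 (-0.78 ± 0.16), Tbx3 (-0.57 ± 0.17) and Klf2 (-0.48 ± 0.11), all transcription factors of the naive state, fell, and the counts adjusted over the list alone were 1 and 3. Among 13 general pluripotency genes the chromatin factor Utf1 rose (0.38 ± 0.11), and Rif1 and Sox2 (-0.29 ± 0.08) fell, with 1 and 3 adjusted over the list alone. A second Sox2 probe stood at 0.14 and was not called, and of 3 Tbx3 probes 2 passed the test. With the set as a block, which rests on the array labelled induced 1, Tbx3 stood at 0.16. Over all alternatives the smallest changes were -0.14 for Klf4, -0.06 for Klf2 and 0.20 for Fbxo15. For Utf1, Sox2 and Rif1 they were 0.04, -0.08 and -0.28. Of the post-implantation epiblast genes, 8 were measured: Otx2 rose (0.84 ± 0.23) and the Wnt receptor gene Fzd2 fell (-0.46 ± 0.14), the same counts as adjusted over the list alone. Otx2 was lower on uninduced 1 to 3 (360.1 to 366) than on every other array (722 to 1105).

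Endoderm lists were not called between the labels, and few of their members were. Of 8 extraembryonic endoderm regulators and receptors, the nuclear receptor gene Hnf4a rose (0.48 ± 0.09) and Amn, part of the cubilin receptor, fell (-0.56 ± 0.14), with 1 and 1 adjusted over the list alone. In the parietal endoderm list of 15, the activin antagonist Fst (at least 2.11-fold, under the limit on 4 of 5 arrays labelled induced) and Snai1 (-0.42 ± 0.09) fell and 0 genes rose, with 0 and 2 adjusted over the list alone. The visceral endoderm list of 9 held 2 falls and 0 rises, the apolipoprotein gene Apoa1 (no fold given, since 1 of 5 arrays labelled uninduced and 4 of 5 labelled induced lay under the limit) and the transferrin gene Trf (-0.62 ± 0.17), as it did adjusted over the list alone. Of 8 definitive endoderm genes, Otx2 and the Wnt inhibitor Sfrp5 (no fold given, with 4 of 5 and 1 of 5 arrays under the limit) rose and Foxa3 (-0.32 ± 0.09) fell, with 2 and 1 adjusted over the list alone. Trf stood at 0.02 with the set as a block.

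Lists of other lineages were not called by camera either. Of 8 primitive streak and nascent mesoderm genes, Wnt3a (0.73 ± 0.15, under the limit on 2 of 5 arrays labelled uninduced) rose and Kdr (at least 1.67-fold, under it on 4 of 5 labelled induced) and Snai1 fell, with 1 and 3 adjusted over the list alone. Kdr, a VEGF receptor, was the only called gene of 12 in the endothelium list, with 0 and 1 adjusted over the list alone. In the neural ectoderm list of 6 and the trophoblast list of 13, 0 genes passed the test, over all probes and adjusted over the list alone. Their most intense members were Nes (0.21 ± 0.23) and Map2 (-0.28 ± 0.14), and Tfap2c (0.20 ± 0.16) and Krt8 (0.53 ± 0.32). Of 3 Tfap2c probes, which lay between 0.12 and 0.78, 1 passed the test. Among 9 germ cell genes Rhox9 (1.38 ± 0.33) and Stk31 (0.29 ± 0.09) rose and 0 fell, with 3 and 2 adjusted over the list alone. Of 6 embryonic fibroblast genes the actin gene Acta2 (at least 2.43-fold) and Twist1 (0.78 ± 0.22) rose and Thy1 (-1.33 ± 0.29) and Prrx1 (at least 1.41-fold) fell, with 4 and 2 adjusted over the list alone. Under the limit were 3 of 5 arrays labelled uninduced for Acta2 and 1 for Twist1, and 4 of 5 labelled induced for Prrx1. A second Acta2 probe stood at 0.16 and was not called. Fry called this list and the ATF4 list (adjusted p = 0.0315 for each). The simple epithelium and tight junction list of 11 held 1 call, a fall of the E-cadherin gene Cdh1 (-0.45 ± 0.12), with 0 and 1 adjusted over the list alone. Prrx1 and Cdh1 each stood at 0.01 with the set as a block. The two-cell-like list had 0 measured members and was not tested.

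Matrix, signalling and metabolic lists held few calls between the labels. Of 18 basement membrane and collagen processing genes, the collagen chaperone gene Serpinh1 fell (-0.62 ± 0.20) and 0 rose, with 0 and 0 adjusted over the list alone. Among 11 Wnt targets, Notum rose (0.51 ± 0.12) and Axin2 fell (-0.68 ± 0.22), both feedback inhibitors of the pathway, with 2 and 3 adjusted over the list alone. Spred2, an inhibitor of Ras signalling, fell (-1.32 ± 0.30, under the limit on 2 of 5 arrays labelled induced) as the only call among 13 Nodal and FGF feedback targets, with 0 and 1 adjusted over the list alone. The BMP target list of 7, the cell cycle list of 15 and the hypoxia and glycolysis list of 15 had 0 calls, over all probes and adjusted over the list alone. Their most intense members were Id1 (0.19 ± 0.34) and Id2 (-0.36 ± 0.36), Mcm4 (-0.11 ± 0.09) and Mcm5 (0.16 ± 0.08), and Gapdh (0.02 ± 0.07) and Slc2a1 (-0.15 ± 0.19). Of 13 p53 targets the stress gene Sesn2 fell (-0.72 ± 0.16) and 0 rose, with 0 and 1 adjusted over the list alone. In the sterol synthesis list of 13, 3 genes rose and 3 fell (4 and 3 adjusted over the list alone), among them the enzyme genes Mvd (0.58 ± 0.17), Idi1 (0.43 ± 0.09) and Sc5d (0.43 ± 0.10) and the regulator Srebf2 (-0.54 ± 0.15). Sox2 was the only call among 9 Sox family genes, with 0 and 1 adjusted over the list alone. Of 13 imprinted genes the amino acid transporter gene Slc38a4 rose (0.69 ± 0.10) and Grb10 (-1.13 ± 0.25) and Nnat (at least 2.23-fold, under the limit on 3 of 5 arrays labelled induced) fell, with 1 and 2 adjusted over the list alone. Serpinh1 stood at 0.19 and Mvd at -0.07 with the set as a block.

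The 24 lists that camera did not call had adjusted p values from 0.759 to 0.995, and from 0.893 to 0.995 with an estimated correlation. Median, mean and test direction differed in sign for general pluripotency (median 0.01, mean -0.15, test down), for epithelium (median -0.06, mean 0.02, test down), for the Sox family (median 0.05, mean -0.05, test down) and for parietal endoderm (median -0.06, mean just above 0, test down). With the set as a block, which in effect sets the array labelled induced 1 against the 5 labelled uninduced, camera called 5 lists with the preset correlation and 0 with an estimated one (adjusted p = 0.843 to 0.866 for these 5 with an estimated correlation). Extraembryonic endoderm regulators had a median of 0.42 (adjusted p = 0.0304), and basement membrane genes 0.23 (adjusted p = 0.00107). BMP targets had a median of -0.61 (adjusted p = 0.0393), hypoxia and glycolysis -0.25 (adjusted p = 0.0391) and cell cycle -0.11 (adjusted p = 0.0271).

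**Figure D3:**
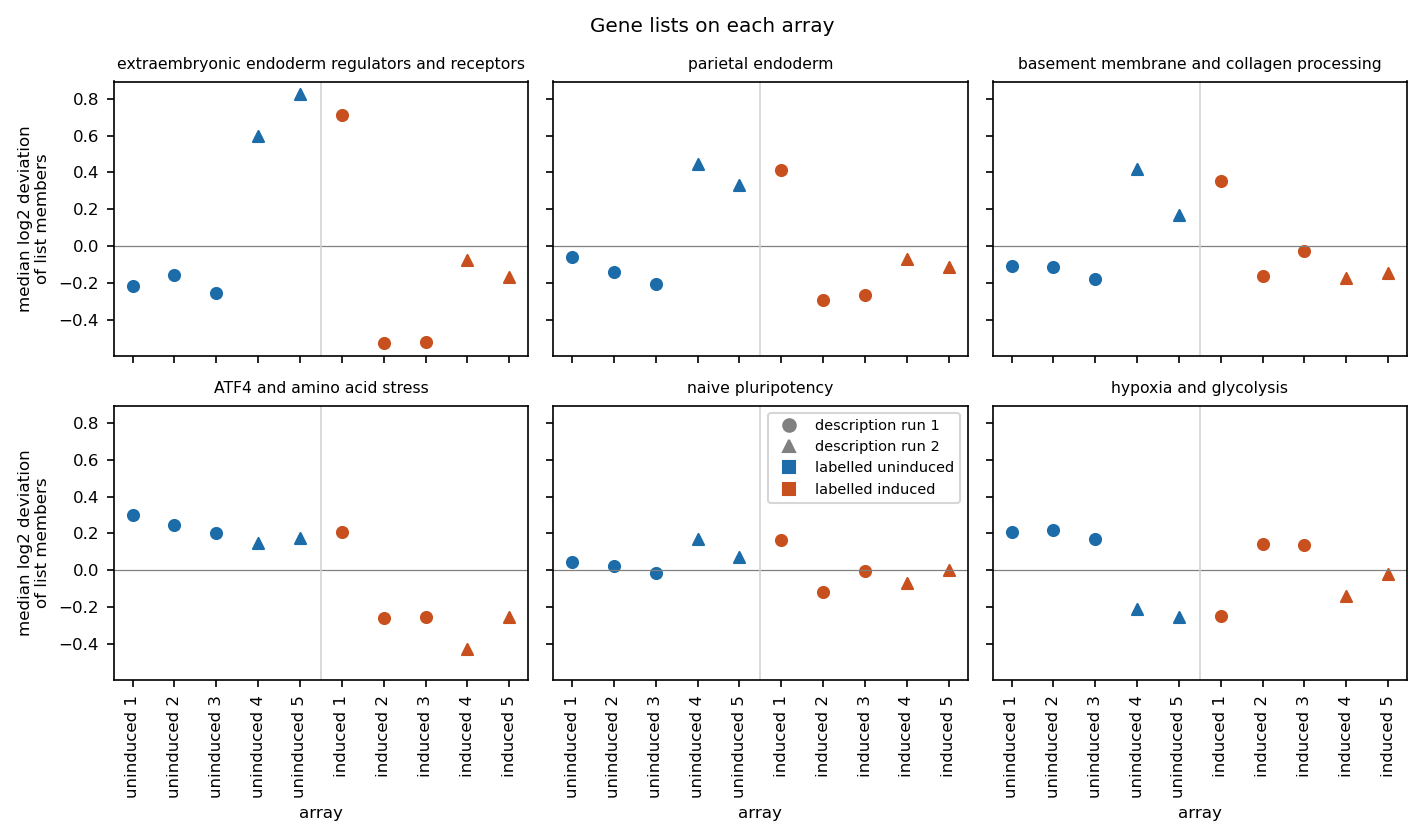
Median log2 deviation of the measured members of 6 gene lists on each array, each gene taken relative to its mean over the 10 arrays, by label (color) and description run (marker shape). ATF4 genes are low on the arrays labelled induced 2 to 5, and the extraembryonic endoderm, parietal endoderm and basement membrane medians are highest on uninduced 4, uninduced 5 and induced 1.

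Single genes of basement membrane and endoderm, among them Col4a1 and Foxa1, differed between the description runs under both labels. The labels do not say what the runs are, and this comparison, its named genes included, was chosen after the values had been seen. It sets uninduced 4 and 5 against uninduced 1 to 3, all in the first set, and induced 4 and 5 against induced 2 and 3, all in the second. The collagen IV gene Col4a1, a basement membrane component, rose from 483 ± 17.5 (SD, n = 3) to 3695 (n = 2) on the arrays labelled uninduced, and from 418 to 2037 (n = 2 each) on those labelled induced. Foxa1, a pioneer transcription factor of endoderm, rose from 19.7 to 180.3 and from 3.57 to 127. In the other direction Anxa2, a membrane-binding annexin, fell from 1013 to 254 and from 1357 to 391. Egln3, a prolyl hydroxylase that is a target of hypoxia signalling, fell from 722 to 224 and from 640.3 to 239.

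Col4a1 rose by 2.89 ± 0.12 (adjusted p = 2.95e-06) in the arrays labelled uninduced and by 2.24 ± 0.13 (adjusted p = 2.93e-05) in those labelled induced, and Foxa1 by 2.47 ± 0.13 and at least 11.99-fold, its induced run 1 arrays being under the background limit. Cyp4f14 was under the background limit on every run 1 array of either comparison and rose at least 14.4-fold and at least 13.5-fold. Olfml3 rose likewise, by at least 12.3-fold and at least 7.78-fold. Further rises, in the order uninduced and induced, were those of Gad1, which makes GABA (2.96 and 2.49), Col4a2 (2.77 and 2.00), the lipid synthesis gene Gpat3 (at least 10.4-fold and 2.26), Fam167a (2.35 and 2.66), the kinase gene Dgkk (2.29 and at least 5.11-fold) and the forkhead factor Foxq1 (2.28 and at least 3.93-fold). Falls were those of Anxa2 (-1.93 and -1.75), the transcription factor genes Zic2 (at least 5.39-fold and at least 3.98-fold lower) and Gata2 (-1.73 and -1.08), Nxph4 (at least 6.27-fold and at least 3.28-fold lower), the uridine phosphorylase gene Upp1 (-1.63 and -1.73) and Egln3 (-1.62 and -1.37). The imprinted gene Dlk1 (-1.57 and -1.86), the repressor Bhlhe40 (-1.57 and -1.46), the vasoactive peptide gene Adm (at least 3.61-fold and at least 8.83-fold lower) and Plekha2 (-1.52 and -1.50) fell too. Some but not all arrays of the dimmer run lay under the limit for Gpat3 (2 of 3, uninduced), Zic2 and Nxph4 (1 of 2, uninduced), and Foxq1 and Adm (1 of 2, induced). A second Egln3 probe, at -0.78 and -0.51, was not called. These 20 genes had been picked for passing the test under the uninduced label, and all 20 passed it under the induced label too.

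Between the runs 1387 probes differed under the uninduced label (695 higher, 692 lower in run 2) and 1121 under the induced label (470 higher, 651 lower). Shared calls numbered 272 higher (21.8 expected for independent calls) and 323 lower (30.1 expected), and 1 probe was called in opposite directions. The correlation of the run changes across the 14985 probes was 0.608 (rho 0.418), over genes that are not independent replicates. The 1387 became 835, 887, 728 and 660 without uninduced 1, 3, 4 and 5, and 2093 with an offset of 50. The 1121 became 598, 573 and 629 without induced 2, 3 and 5.

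**Figure D4:**
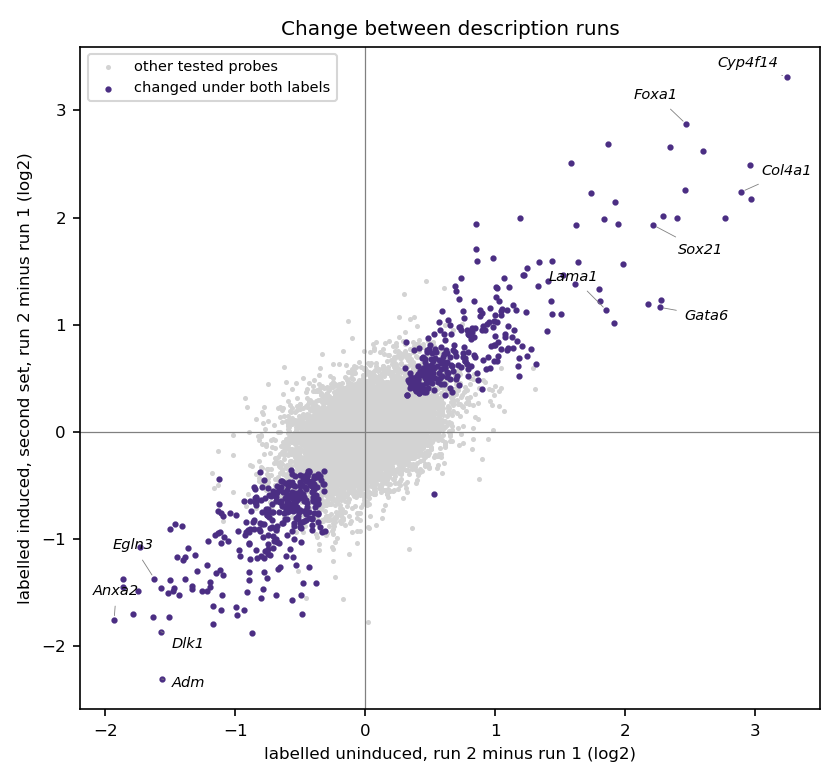
Run 2 minus run 1 log2 change of each tested probe on the arrays labelled uninduced (horizontal) and on the second-set arrays labelled induced (vertical), with probes called under both labels in purple. The changes correlate across probes (r = 0.608), and Col4a1 and Foxa1 lie high on both axes.

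The parietal endoderm, extraembryonic endoderm and basement membrane lists rose in run 2 under the uninduced label by camera with the preset correlation, and the visceral and definitive endoderm lists were not called. Of 15 parietal endoderm genes, 8 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 6.96e-07, and adjusted p = 0.0657 with an estimated correlation). They included the laminin gene Lama1 (1.85 ± 0.11) and the aspartic protease gene Pga5 (1.95 ± 0.12). Among 8 extraembryonic endoderm regulators and receptors 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 3.52e-05, and adjusted p = 0.0657 with an estimated correlation). These held the transcription factors Gata6 (2.27 ± 0.13) and Sox7 (0.90 ± 0.08), the growth factor receptor gene Pdgfra (1.91 ± 0.12) and Bmp6 (at least 3.38-fold). Of 18 basement membrane genes 7 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 2.68e-06, and adjusted p = 0.105 with an estimated correlation), among them the perlecan gene Hspg2 (0.99 ± 0.11). Visceral endoderm genes counted 2 rises and 1 fall of 9 (2 and 1 adjusted over the list alone; camera adjusted p = 0.413), with a median just under 0, a mean of 0.12 and the test's direction up. Definitive endoderm genes counted 2 rises and 1 fall of 8 (2 and 2 adjusted over the list alone; camera adjusted p = 0.779), with a median of -0.10, a mean of 0.25 and the test's direction up. The parietal and basement membrane lists share Col4a1, Col4a2, Lama1, Lamb1, Lamc1, Nid1 and Sparc.

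Under the induced label, 5 parietal endoderm genes rose and 1 fell in run 2 (5 and 2 adjusted over the list alone; camera adjusted p = 0.0485, and adjusted p = 0.294 with an estimated correlation). The list's median was -0.10, its mean 0.42 and the test's direction up. Rises were found for Lama1 (1.14 ± 0.12), Pga5 (1.94 ± 0.13), Gata6 (1.16 ± 0.14), Pdgfra (at least 3.26-fold, under the limit on 1 of 2 run 1 arrays) and Bmp6 (at least 2.02-fold), while Hspg2 stood at 0.34 ± 0.12. Extraembryonic endoderm genes counted 3 rises and 1 fall (3 and 2 adjusted over the list alone; camera adjusted p = 0.166), and basement membrane genes 3 and 3 (4 and 3 adjusted over the list alone; camera adjusted p = 0.987), with a median of -0.13, a mean of 0.12 and the test's direction up. Visceral endoderm genes counted 1 rise and 2 falls (1 and 3 adjusted over the list alone; camera adjusted p = 0.124). Definitive endoderm genes counted 1 and 1 (1 and 2 adjusted over the list alone; camera adjusted p = 0.867), with a median of -0.14, a mean of 0.09 and the test's direction down. The difference between the labels in run change was tested itself and passed for 2 probes, with 1766 at an unadjusted p under 0.05. Sox7 rose under the uninduced label and stood at -0.26 under the induced one (difference -1.15 ± 0.12, adjusted p = 0.0285). The other was 2210409E12Rik, at 0.02 under the uninduced label and -1.77 under the induced one (difference -1.79 ± 0.17, adjusted p = 0.0285).

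The hypoxia, Wnt target and imprinted lists fell in run 2 under both labels, and the BMP target list under the uninduced label, by camera with the preset correlation. All of these calls were lost with an estimated correlation: adjusted p = 0.0657 and 0.146 for the hypoxia list, 0.105 and 0.131 for the Wnt list, 0.143 and 0.204 for the imprinted list and 0.105 for the BMP list. Of 15 hypoxia and glycolysis genes, 0 rose and 8 fell under the uninduced label (1 and 12 adjusted over the list alone; camera adjusted p = 2.68e-06) and 0 and 7 under the induced label (0 and 9 adjusted over the list alone; camera adjusted p = 1.0e-04). With Egln3, they included the glycolytic genes Pfkp (-0.93 and -0.65), Tpi1 (-0.68 and -0.56) and the glucose transporter gene Slc2a1 (-0.62 and -0.62). Under the induced label 2 of 3 Tpi1 probes passed the test. Of 11 Wnt targets 0 rose and 6 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.00723), and under the induced label 0 and 7 (0 and 7 adjusted over the list alone; camera adjusted p = 1.0e-04), with Lef1 at least 2.70-fold and at least 2.00-fold lower, Axin2 at -0.85 and -0.53 and Myc at -0.75 and -0.97. BMP targets held 1 rise, of Id4, and 3 falls of 7 under the uninduced label (1 and 4 adjusted over the list alone; camera adjusted p = 0.00723), and 2 and 3 under the induced label (2 and 4 adjusted over the list alone; camera adjusted p = 0.166). Id4 rose at least 3.80-fold, under the limit on 1 of 3 run 1 arrays, and at least 5.18-fold, while its relatives Id1 (-1.13 and -0.74) and Id2 (-1.41 and -0.87), all inhibitors of differentiation, fell with Gata2, though a second Id2 probe stood at -0.03 under the induced label and was not called. Imprinted genes counted 1 rise and 6 falls of 13 under the uninduced label (1 and 7 adjusted over the list alone; camera adjusted p = 0.00547) and 0 and 6 under the induced label (1 and 7 adjusted over the list alone; camera adjusted p = 0.00555), with Cdkn1c, a cell cycle inhibitor, at -1.33 and -1.47.

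Of 13 p53 targets 0 rose and 2 fell under each label, Pmaip1 (-1.50 and -1.38) and Cdkn1a (-0.63 and -0.76), which act in apoptosis and cell cycle arrest; of 3 Cdkn1a probes 2 passed the test under each label. Adjusted over the list alone, 4 and 3 fell, and camera called the list (adjusted p = 0.00678 and adjusted p = 0.0266) but not with an estimated correlation (adjusted p = 0.184 and adjusted p = 0.294 with an estimated correlation). The cell cycle list was called under the uninduced label (camera adjusted p = 0.00547, and adjusted p = 0.105 with an estimated correlation), with a median of -0.16 and 1 call, a fall of the cyclin gene Ccne2 (-0.51 ± 0.12), also adjusted over the list alone. Under the induced label the epithelium list held 0 rises and 5 falls of 11 (1 and 5 adjusted over the list alone; camera adjusted p = 0.00555, and adjusted p = 0.146 with an estimated correlation). There the epiblast list held 1 rise and 5 falls of 8 (1 and 5 adjusted over the list alone; camera adjusted p = 0.0266, and adjusted p = 0.204 with an estimated correlation), among them the POU factor Pou3f1 (-1.11 ± 0.10). In all, camera called 9 lists between runs under the uninduced label and 7 under the induced label, and with an estimated correlation it called 0 and 0.

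Sox17 itself rose between the runs on the arrays labelled uninduced (0.73 ± 0.08, adjusted p = 0.000759) and stood at 0.15 ± 0.09 on the second-set arrays labelled induced (adjusted p = 0.403). Those second-set arrays read 11.99 to 16.6, near the background limit of 10.6, where a fall is hard to see. A rise can be seen from there, since Foxa1 rose from 3.57 to 127 on the same arrays. The array labelled induced 1, in the first set and in run 1 by its description, read 67.3 for Sox17. Uninduced run 1 read 30.5 to 32.6, and uninduced run 2 read 60.6 and 65.3. The log2 difference of induced 1 was 0.80 from uninduced run 1 and 0.08 from uninduced run 2. No p value is given for these, because this 1 array was singled out for its Sox17 value. The Col4a1 intensity of induced 1 was 3577 and its Foxa1 intensity 184. Against uninduced run 1, with this lone array assumed to vary like the arrays of the other groups, it differed at 647 probes (339 higher, 308 lower), and against uninduced run 2 limma called 0 probes (987 at an unadjusted p under 0.05). On simulated data the latter comparison recovered 79% of 2-fold and 97% of 4-fold changes.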

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

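The tests of the array set, Sox17 induction, array background, title order, fibroblast cells and culture were chosen only after the result was seen, while those on other splits of the arrays were planned. A gene was marked here when 1 of the 5 arrays of a label lay far from the rest, by the gap to its nearest neighbor divided by the whole range (critical value 0.71). This held for 26 of 292 gene groups, where chance marks about 1 in 20, or 14.6, and for 23 of them the array was the one labelled induced 1. It stood high among the arrays labelled induced for Sox17 (0.859), Nfatc3 (0.728), Abcg4 (0.875), Tbx3 (0.825), Map2 (0.757), Spred2 (0.775), Prrx1 (0.825), Cdh1 (0.899), Chac1 (0.935), Mthfd2 (0.742), Nupr1 (0.738), Sox7 (0.795), Tek (0.742) and Tex14 (0.728). It stood low for Olfr536 (0.842), Jph2 (0.740), Defb25 (0.921), Fam20c (0.860), Dsg4 (0.713), Phf8-ps (0.711), Grb2 (0.754), Twist1 (0.766) and Sc5d (0.743), and on the first component of the receptor probes (0.802) and of the tested probes (0.833). Among the arrays labelled uninduced, array 1 stood apart for Fam20c (0.816), array 5 for Kdr (0.775) and array 4 for Nes (0.725). By a test of the difference itself, the run change differed between the labels for 2210409E12Rik (-1.79) and Sox7 (-1.15).

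Between the labels 2919 probes and 148 genes at least 2-fold differed, and Sox17 stood at -0.66 on the arrays labelled induced (exact permutation p = 0.135). Chance cannot be excluded for the 1358 higher probes (6 of 100 splits as many, here and below with the labels' own, highest other 2056), the 1561 lower probes (5 of 100, highest other 2056) or the 1 list (64 of 100, highest other 10). All splits with as many higher or lower probes keep the second-set arrays together. Of 7 splits with at least 100 called probes, 6 do so. The other sets uninduced 1 to 3 and induced 2 and 3 against the rest (646 called). The probe counts thus follow a structure of the samples. For the 148 genes chance can be excluded only if arrays are exchangeable across the sets (2 of 100, highest other 154). Of the 6 splits that keep the second-set arrays together, 2, the labels included, give as many (range 118 to 154), which points to the same structure. An array set difference and the label cannot be told apart: with the set as a block the median change of the called probes went from 0.55 to 0.12, but that value rests on the array labelled induced 1 alone, whose title is in doubt. Induction of Sox17 and its absence cannot be told apart either, since Sox17 did not pass the test (-0.66) and the probes' place relative to the transgene is unknown, and a difference in culture or array processing between the sets stays open.

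Between the description runs Col4a1, Col4a2, Foxa1, Gata6 and many other genes changed the same way under both labels. Array background would also move the receptor probes alike, yet their run changes correlated at -0.0539 between the labels, and fibroblasts would bring their collagens, yet the highest run 2 mean of a Col1a1, Col1a2 or Col3a1 probe was 9.86, under the stricter background limit of 15.0. A candidate explanation is that the titles are out of step with the arrays, so that runs rather than labels part the induced from the uninduced cells within a set. The array labelled induced 1 differed from uninduced run 1 as the second set's runs differ (correlation 0.581 across probes, 0.0116 for its difference from uninduced run 2), and Sox17 was highest on it and on uninduced 4 and 5. That induced 1 lay with uninduced 4 and 5 had been seen first, so these values restate it and are not a separate test of the titles. In the second set Sox17 itself did not pass the test between the runs (0.15, adjusted p = 0.403). Its readings there, 11.99 to 16.6, lay near the background limit of 10.6, where a fall is hard to see but a rise is not. Foxa1 rose on the same arrays from 3.57 to 127. A Sox17 rise like that under the uninduced label (0.73) was therefore not seen in the second set. Whether the probes see the transgene is unknown, so that result does not decide for or against the titles. A culture difference between the runs stays open and untested.

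The ATF4 and amino acid stress list was low on the arrays labelled induced 2 to 5, with a median of -0.72 over its 6 called members. With the set as a block that median was -0.14 (members from -0.20 to 0.00), a value that rests on the array labelled induced 1 alone. The array set, a culture difference between the sets and the label therefore cannot be told apart as sources of the fall, because 0 arrays labelled uninduced lie in the second set and the title of its 1 counterpart in the first is in doubt. What parts the sets stays open.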

How the results depend on the processing

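The tests with the stricter filter, the offset of 50, the floor at the background limit and the array set were chosen only after the result was seen, as was the run comparison. Outside the set settings, 1638 of 1640 named gene values and 1420 of 1420 for called genes kept their sign. The called genes had been picked from these same arrays, so a kept sign is little evidence of robustness. The call itself was lost in 417 values with an array left out and in 65 within run 1 alone. Of list values, 510 of 548 kept camera's direction and their side of the threshold. Of the rest, 32 turned direction, 0 of them called by camera, and 6 kept it and were newly called. The replicate block called 1509 higher and 1835 lower probes, 153 genes at least 2-fold and 1 list, with Sox17 at -0.66. No filter gave 289, 260 and 35 genes, where more probes were tested. An offset of 50 gave 29 genes and 2093 run probes (uninduced), and the floor 379 genes. Run 1 alone gave 0, 0 and 0 by limma (2987 at an unadjusted p under 0.05), with 6 arrays. Run 2 alone, where label and set coincide, gave 2044, 2356, 429, 7 lists and Sox17 at -1.31. Array weights gave 3607, 3706, 318 and Sox17 at -0.77, with a weight of 0.169 for induced 1. Probes whose groups do not overlap numbered 474 higher and 552 lower (chance share 0.794%). An estimated correlation called 0 lists and fry 2. The set as a block and the first set alone both rest on induced 1 alone against 5 arrays, and gave the same changes for the genes named next. With the set as a block limma called 0, 0 and 0 (724 at an unadjusted p under 0.05) and camera 5 lists (0 with an estimated correlation). There the sign turned for the called genes Tbx3 (0.16), Trf (0.0194), Serpinh1 (0.19), Prrx1 (0.00899), Cdh1 (0.0144) and Mvd (-0.0719), and for Sox17 (0.51), Nes (-0.55), Map2 (0.29), Krt8 (-0.38), Id1 (-0.80) and Gapdh (-0.00262), which had not passed the test. Camera's direction turned there for lists it then called, extraembryonic endoderm (median 0.42), basement membrane (0.23), BMP target (-0.61) and cell cycle (-0.11), and for lists it did not call, naive pluripotency (0.0620), general pluripotency (0.0119), parietal endoderm (0.28), definitive endoderm (-0.13), primitive streak (0.0361), trophoblast (-0.16), Wnt target (-0.16), sterol synthesis (-0.0452) and, with the block only, simple epithelium (0.0144). Uncalled turns elsewhere, where a median may keep its sign, were definitive endoderm (-0.00289), neural ectoderm (-0.00512), Wnt target (-0.0763) and fibroblast (-0.0808) without the filter, definitive endoderm (-0.13) with the stricter one, neural ectoderm with the offset (0.0229) and the floor (0.0474), Wnt target with the replicate or run block (0.00809 in each), and general pluripotency (0.00956) and Sox family (0.10) with averaged probes. In run 1 they were Id1 (-0.18), naive pluripotency (-0.0466), extraembryonic (0.11), parietal (0.16) and visceral endoderm (0.0909), endothelium (-0.0849), basement membrane (0.18), Wnt target (0.0488), BMP target (-0.0828) and cell cycle (0.00614), and in run 2 Id2 (0.18), neural ectoderm (-0.32) and hypoxia (0.0401). Leaving out 1 array gave 12 to 3390 higher probes, 2 to 3431 lower, 2 to 329 genes, 1 to 1 list and Sox17 from -0.95 to -0.54. It also turned the direction of 5 uncalled lists, with medians from -0.18 to 0.22 (Sox family), -0.24 to 0.0568 (basement membrane), -0.56 to -0.12 (extraembryonic endoderm), -0.20 to -0.0699 (imprinted) and -0.0239 to 0.12 (neural ectoderm). It gave 660 to 1387 and 573 to 1121 run probes and a run correlation of 0.539 to 0.608. Called probes numbered 21, 34, 52 and 1864 without uninduced 1 to 4, and 6821, 17, 639, 14 and 16 without induced 1 to 5. The cause was not tested. Not run were neqc background, no background correction, median scaling, detection filters and slide blocks, which need signals tied to samples or slides that the labels do not give. Under the limit of 10.6 a change cannot be measured.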

Other observations

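All tests in this part concern the run comparison and were chosen only after the result was seen, with the genes named here. Several single genes of trophectoderm and simple epithelium fell in run 2 under both labels. The keratin genes Krt8 (-0.71 ± 0.11 SE uninduced, -1.09 ± 0.12 induced), Krt18 (-0.92 and -0.94) and Krt19 (to below the background limit uninduced, at least 5.53-fold lower induced, with 1 of 2 run 2 arrays under the limit), the desmosome gene Pkp2 (-0.78 and -0.86) and the trophectoderm factors Cdx2 (at least 1.37-fold lower and -0.91) and Dlx3 (-1.09 and -0.79) all passed the test. Tfap2c, another factor of that lineage, rose (0.47 and 0.55). Of 13 trophoblast genes, 1 rose and 5 fell under the uninduced label (4 and 5 adjusted over the list alone), and 4 rose and 5 fell under the induced label (4 and 5 adjusted over the list alone). Camera called the trophoblast list under neither label (adjusted p = 0.160 and adjusted p = 0.411). It did not call the epithelium list under the uninduced label either (adjusted p = 0.160), where 0 rose and 4 fell of 11 (1 and 5 adjusted over the list alone), with a median of 0.03, a mean of -0.26 and the test's direction down.

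Among pluripotency and signalling genes, the naive marker Dppa3 rose in run 2 (0.57 ± 0.09 SE uninduced, 1.03 ± 0.09 induced) and the growth factor gene Fgf4 fell (-0.60 and -0.75). The Nodal inhibitors Lefty1 (-0.51 and -0.79) and Lefty2 (-0.89 and -1.04) fell, while the MAP kinase phosphatase gene Dusp4 rose (1.22 and 1.46; 2 and 3 of 3 probes passed the test). In the Sox family Sox21 rose (2.21 and 1.93) and Sox18 fell (-0.93 and at least 5.48-fold, with 1 of 2 induced run 2 arrays under the limit). Of the 15 genes of the ATF4 list 1 rose and 2 fell under each label (adjusted over the list alone 2 and 3 uninduced, 1 and 6 induced), among them the asparagine synthetase gene Asns, which rose (0.52 and 0.55), and the mTOR inhibitor Ddit4, which fell (-1.43 and -1.52), while camera did not call the list (adjusted p = 0.397 and 0.166). The primitive streak and sterol synthesis lists held 0 calls between the runs under either label by limma, over all probes and adjusted over the list alone.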
